A study of Homo sapiens with 15 samples.

How the data were processed

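Total RNA of MCF10A cells in 5 glutamine conditions, with 3 biological replicates each, was depleted of ribosomal RNA (RiboErase) and made into libraries with a KAPA HyperPrep kit. ERCC spike-ins were added and the libraries were read on a NextSeq instrument, per the labels. The deposited table, made by the authors, holds integer counts per gene and library for 62754 Ensembl genes and 92 ERCC spike-ins, and the labels name GRCh38.p14. The counts were used as deposited. The aligner and counting settings and the strand rule are not given in the sources used here. All 15 columns were matched to a sample and 0 were left over. Depth per library was 3704170 to 13361406 gene counts, and spike-ins took 1.03 to 1.58% of all counts. Gene symbols were found for 42343 genes, and coordinates are those of the GRCh38.p14 RefSeq annotation. GC content, transcript length and exonic overlap came from GENCODE 29, whose gene set may differ from the one used for counting. The proteome named in the series title was not used here.

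Before the data were examined, the groups, comparisons, tests, gene lists, the rule for named genes and a first set of alternatives were fixed. The planned test was edgeR 4.0.16 under R 4.3.3: filterByExpr on the 5 groups (minimum count 10, minimum total 15), which kept 13828 genes with at least 99.72% of the counts of each library, TMM factors, 1 quasi-likelihood fit of all 15 libraries with 1 term per group, and Benjamini-Hochberg adjusted p under 0.05 with no fold threshold. Each limited concentration was compared with full medium, the limited ones with each other (0.04 with 0.28 and with 0.12 mM, 0.12 with 0.20 mM and 0.20 with 0.28 mM), and a slope over log2 concentration was fitted in the 12 limited libraries. CPM values use TMM-scaled library sizes, and log2 CPM for components a prior count of 2.

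The replicate numbers were then tested for pairing, with the group means removed. All 30 pairs of libraries that share a number correlated above 0.1 (r 0.184 to 0.489), libraries with different numbers had r from -0.406 to 0.0549, and 15 of 15 libraries correlated best with one of their own number. Components 1 and 2 held 24.6 and 13.4% of the variance, 88.7 and 80.3% of it between replicate numbers, and component 3 held 11.8%, 71.8% of it between groups. The replicate number was therefore added as a block, and the report gives this fit beside the planned one. What the numbers stand for (a day, a passage or a library batch) is not stated in the labels. Repeating the alternatives and applying the named-gene rule to the fit with the block was decided after this check.

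Named genes are, for 0.04 mM against full medium, the 10 that rose and the 10 that fell most among genes with adjusted p under 0.05, a mean of at least 5 CPM, a symbol and no overlap between the 2 groups, and 5 each way in the other comparisons. The 15 genes ASNS, ATF4, DDIT3, CHAC1, TRIB3, SESN2, PSAT1, PHGDH, GLUL, SLC1A5, SLC7A11, SLC38A2, TXNIP, MYC and CDKN1A are named in every comparison with full medium, and up to 4 members with the smallest adjusted p exemplify a list. For 2 genes that these rules name, results are not reported here. Genes outside the rule are marked where they appear.

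The 42 gene lists were written from general knowledge of the pathways and tested with camera of limma 3.58.1 (preset correlation 0.01, BH over 168 tests), with the correlation estimated from the data, and with the self-contained fry. The lists share members: 6 genes are in both the ATF4 and the amino acid transporter lists, 6 in both the glutamine enzyme and nucleotide lists, and 5 each in the ribosome biogenesis and MYC-linked, the immediate early and ERK, and the p53 and cell death lists. List medians are from the fit with the block. The list called MondoA targets also holds starvation regulators, so its results are not those of MondoA targets alone.

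Alternatives were DESeq2 1.42.0, its size factors in edgeR, scaling to the summed ERCC counts, no filter beyond 1 count, a filter of 5 CPM in 3 libraries, the 2 compared groups alone, each library left out, and, for the slope, all 15 libraries. Added after the data were seen were thinning of all libraries to the 3704170 counts of the shallowest, offsets per library from a spline (4 degrees of freedom) on GC content, length or both, leaving out the 2 libraries with over 1% mitochondrial rRNA, and leaving out replicate 3 in all groups. Other splits of the samples were fitted: 10 of 3 against 3, the 4 that part 3 pairs for the fit with the block, and 100 orders of the concentrations for the slope. Sharing of called genes among concentrations was set against 20 simulations of unchanged groups with the same controls. Python 3.11.15 handled tables and matplotlib 3.10.9 drew figures.

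The code was tested on simulated data, with 200 of 13828 genes changed at 0.04 mM. With the block edgeR found 72% of changes of 1 and 51% of 0.5 (log2), with 15 false calls among 138, above the 5% aimed for. Without the block it found 54 and 7%, with 1 false among 62, and DESeq2 with the block found 70 and 45%, with 6 false among 121. A shift of 0.3 in 30 genes was found by camera with an estimated correlation (p = 5.83e-06 with the block and 4.86e-06 without). Power for real lists, whose genes may vary together, was not tested.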

Results

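RNA was measured by sequencing in MCF10A, a human breast epithelial cell line. Cells grew in full medium (2.5 mM glutamine) or with 1 of 4 lower concentrations, 0.28, 0.20, 0.12 or 0.04 mM, with 3 biological replicates per group (15 libraries). Gene counts per library, for replicates 1, 2 and 3, were 11228596, 6454088 and 3704170 at 0.04 mM and 13199140, 8666765 and 5148795 at 0.12 mM. They were 11833646, 8758587 and 8762578 at 0.20 mM, 13361406, 8420992 and 8140642 at 0.28 mM, and 11442044, 9183710 and 7451107 in full medium. Libraries with the same replicate number resembled each other across groups, so each value is given from the fit with the replicate number as a block. The fit without it is named where it is meant. Changes are log2 fold changes with 1 standard error, from 3 libraries per group, and adjusted p-values are from edgeR's quasi-likelihood test with the Benjamini-Hochberg correction over 13828 genes. A gene is said to rise or fall only where its adjusted p is under 0.05.

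At 0.04 mM against full medium, the transcripts that handle glutamine moved in both directions. GLUL, which encodes the enzyme that makes glutamine, fell from a mean of 390 to 261 CPM (library-scaled counts, SD 51.8 and 27, log2 change -0.58, SE 0.0721, adjusted p = 2.58e-06, lower in 3 of 3 pairs). SLC38A2, a glutamine and neutral amino acid importer, rose from 318 to 501 CPM (SD 52.5 and 114; 0.65, SE 0.0714, 4.59e-07). GFPT2, which uses glutamine to start hexosamine synthesis, rose from 14.6 to 40.3 CPM (SD 0.373 and 10.1; 1.41, SE 0.139, 1.41e-07). GLUL is ENSG00000135821 (chromosome 1, 182378098 to 182391790, GRCh38.p14). SLC38A2 is ENSG00000134294 (chromosome 12, 46358188 to 46372773) and GFPT2 is ENSG00000131459 (chromosome 5, 180300698 to 180353336). Without the block, of these 3 only GFPT2 passed the test (1.44, SE 0.244, adjusted p = 0.0401). GLUL and SLC38A2 had adjusted p = 0.116 and 0.231.

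Besides GFPT2, 5 genes passed both with and without the block at 0.04 mM. SLITRK6 (ENSG00000184564, chromosome 13, 85792790 to 85799419), a membrane protein known from neurite growth, rose by 1.24 (SE 0.153, adjusted p = 2.5e-06; without the block 1.27, SE 0.182, 0.0147). ITGA2 (ENSG00000164171, chromosome 5, 52989352 to 53094779), a subunit of a collagen receptor, rose from 116 to 222 CPM (0.94, SE 0.0956, 1.99e-07; without the block 0.94, SE 0.134, 0.0147). PIK3CD (ENSG00000171608, chromosome 1, 9627258 to 9729114), a catalytic subunit of phosphoinositide 3-kinase, rose by 0.97 (SE 0.127, 6.54e-06; without the block 0.98, SE 0.166, 0.0401). The ion channel gene TRPV3 (2.30 without the block, adjusted p = 0.0381, mean 3.015 CPM) and the unnamed gene ENSG00000233589 (1.24, adjusted p = 0.0401, uncertain because its exons overlap another gene) complete the 6 genes that rose without the block. Both were named after their values were seen. With the block the steepest named changes also included CXCL8, a neutrophil attractant (1.67, SE 0.225), and MMP9, a gelatinase (1.49, SE 0.24). They also held MCF2, a guanine exchange factor (1.36, SE 0.246), ARNT2 (1.23, SE 0.19) and COL6A3, a collagen chain (1.19, SE 0.144). HSD17B2, a steroid dehydrogenase, rose by 1.6 (SE 0.31) and the long non-coding LINC02454 by 1.33 (SE 0.232). The named genes that fell furthest were RGS16 (-1.10, SE 0.256), EME1, a repair endonuclease subunit (-1.04, SE 0.204), H3-7 (-0.95, 37.4% exonic overlap, uncertain) and MMAA (-0.89, SE 0.23). Behind them came LHFPL6 (-0.88, SE 0.213), SLITRK5 (-0.85, SE 0.232), and PLD6 (-0.84, SE 0.232, 24.4% exonic overlap, uncertain). TMEM141 (-0.83, SE 0.231), LIAS, a lipoic acid synthase (-0.80, SE 0.169), and CCDC61 (-0.78, SE 0.203) fell as well. Single libraries left out ended some of these calls, with adjusted p from 0.0528 to 0.126: RGS16 without 0.04 mM replicate 2 (-0.73), MMAA without 0.04 mM replicate 1 or full medium 3 (-0.77 and -0.74) and CCDC61 without 0.04 mM replicate 3 (-0.66). The others were SLITRK5 without 0.04 mM replicate 2 or 3 or full medium 2 (-0.61 to -0.72), PLD6 without 0.04 mM replicate 2 or full medium 2 (-0.679 and -0.635) and TMEM141 without either of these or full medium 3 (-0.676 to -0.695). MT-RNR2, the large mitochondrial ribosomal RNA, rose by 4.33 (SE 1.28, adjusted p = 0.0214; 2.44 to 4.78 and not past the test without 0.04 mM replicate 2 or 3 or full medium 1 or 3), with an SD of 10100 CPM around a mean of 5970 CPM, and replicate 3 at 0.04 mM held 2.97% of its counts in mitochondrial ribosomal RNA.

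**Figure D1:**
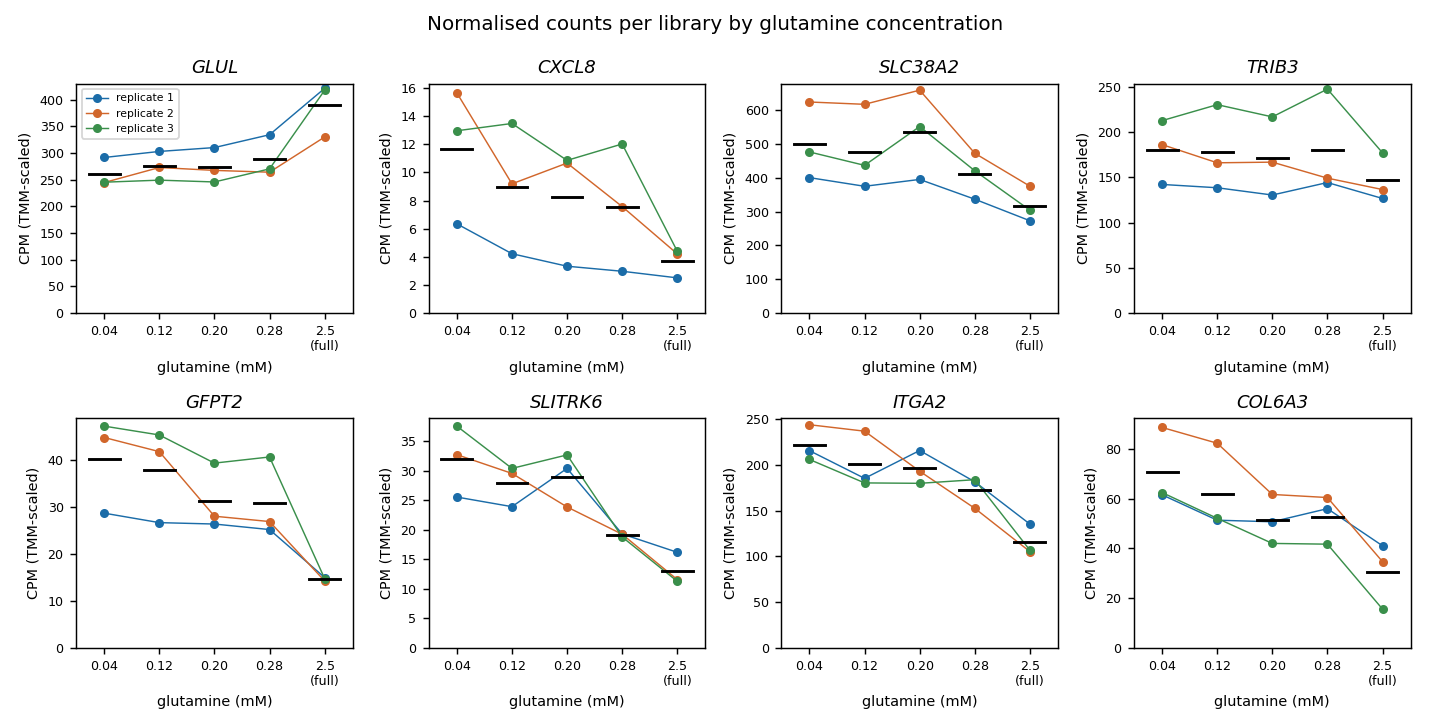
CPM of 8 genes in each of the 15 libraries, with lines joining libraries of the same replicate number and black bars at the group means. The 8 genes were picked after their values were seen.

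Of the stress response genes chosen before the data were examined, TRIB3, an inhibitor induced by amino acid shortage, rose by 0.30 at 0.04 mM (SE 0.0765, adjusted p = 0.00838). PHGDH, the first enzyme of serine synthesis, rose by 0.39 (SE 0.106, 0.0113, higher in 2 of 3 pairs). SLC7A11, the cystine importer, rose by 0.51 (SE 0.109, 0.00171), and TXNIP, a glucose uptake inhibitor, by 0.31 (SE 0.0869, 0.0156). TRIB3 did not pass without 0.04 mM replicate 2 (0.21, 0.13) or full medium 3 (0.25, 0.0507), PHGDH without replicate 3 of 0.04 mM (0.26, 0.147) or of full medium (0.21, 0.185), and TXNIP without replicate 1 of 0.04 mM (0.16, 0.335) or of full medium (0.24, 0.0915). ATF4 itself had 0.23 (SE 0.0826, 0.0636), CHAC1 1.32 (SE 0.563, 0.118) and ASNS 0.71 (SE 0.607, 0.482), none of them past the test. ASNS stood at 1.49 CPM at most in any group mean and 44.6% of its exons overlap another gene, so it is uncertain here. DDIT3 (0.19, SE 0.439, 39.6% overlap and so uncertain), SESN2 (0.12, SE 0.111), and PSAT1 (0.16, SE 0.0861) did not pass either. Nor did SLC1A5 (0.11, SE 0.0658, 23.8% overlap, uncertain), MYC (-0.063, SE 0.0677) and CDKN1A (0.073, SE 0.0708), with adjusted p from 0.221 for PSAT1 to 0.827 for DDIT3. Without the block none of these genes passed at any concentration.

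Among the gene lists, those of growth and division fell at 0.04 mM. All 38 replication-dependent histone genes, which package newly made DNA, fell (median -0.467, 38 over all genes and 38 adjusted over the list alone; camera adjusted p = 3.47e-38, but 0.293 with an estimated correlation), led by H2BC9 (-0.66, SE 0.0741). Copies of these genes are near identical, so single members are uncertain. Ribosome biogenesis genes fell as a list (median -0.189, 16 of 46 fell over all genes and 22 over the list alone, adjusted p = 7.19e-13, and 0.357 with an estimated correlation), with NOP56 at -0.47 (SE 0.0686). So did mitochondrial ribosomal proteins (median -0.213, 20 of 75 and 26, 4.4e-09 and 0.413) and cytosolic ribosomal proteins (median -0.132, 14 of 77 and 15, 5.34e-08 and 0.568). G2 and M phase genes fell (median -0.186, 22 of 53 and 27, 9.81e-07 and 0.437), with the mitotic activator CDC20 at -0.71 (SE 0.0879). S phase genes fell (median -0.162, 16 of 43 and 18, 0.000167 and 0.506), with the replication factor CDC45 at -0.49 (SE 0.101). Proteasome subunits (median -0.154, 8 of 32 and 13, 4.25e-06 and 0.413), MYC-linked growth genes (-0.167, 8 of 22 and 11, 1.1e-05 and 0.413), and nucleotide synthesis (-0.155, 11 of 30 and 13, 0.00119 and 0.413) fell. The nuclear-encoded respiratory chain (-0.107, 9 of 76 and 9, 0.000416 and 0.573), translation factors (-0.123, 8 of 39 and 8, 0.00478 and 0.497) and snoRNA host genes (-0.184, 3 of 14 and 4, 0.0231 and 0.562, but 0.0523 with a GC and length offset) also fell. Within them the spermidine synthase gene SRM had -0.46 (SE 0.0677) and the proteasome ATPase gene PSMC4 -0.36 (SE 0.0742). Against the direction of their lists, 2 nucleotide synthesis genes and 1 MYC-linked gene rose over all genes, and over each list alone 4 nucleotide synthesis, 1 MYC-linked, 3 S phase, 2 G2 and M phase and 1 cytosolic ribosomal protein gene. All 12 of these lists also fell without the block, with adjusted p from 1.57e-25 to 0.0223.

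The lists that rose at 0.04 mM hold signalling, redox and amino acid genes. ERK output genes had a median of 0.185 (8 of 20 rose over all genes and 10 over the list alone; camera adjusted p = 2.02e-06, and 0.412 with an estimated correlation), with the EGF receptor ligand gene AREG at 0.61 (SE 0.0752) and PHLDA1 at 0.65 (SE 0.0901). Inflammatory and NF-kB genes rose (median 0.241, 6 of 22 and 10, 2.39e-05 and 0.357), among them BIRC3 (0.68, SE 0.102) and IL1A (0.67, SE 0.136). NRF2 targets rose (median 0.192, 10 of 25 and 14, 0.000125 and 0.412), among them NQO1, a quinone reductase (0.43, SE 0.0767). The NRF2 target AKR1C1 also rose (0.68, SE 0.107) but has close paralogs and is uncertain. ATF4 and amino acid response genes rose (median 0.22, 10 of 41 rose and 2 fell, 15 and 2 over the list alone, 5.3e-05 and 0.413; median 0.133, 8 rising and 0.00409 without the 2 libraries with most mitochondrial rRNA), with the tRNA exporter gene XPOT at 0.47 (SE 0.0714) and ADM2 at 2.97 (SE 0.542, 0.478 CPM in full medium). Amino acid transporters (0.163, 6 of 26 rose and 7 over the list alone, 0.00069 and 0.293), mitochondrially encoded mRNAs (0.37, 6 of 13 and 9, 5.22e-07 and 0.413) and YAP targets (0.154, 3 of 19 and 8, 0.00263 and 0.412) rose. Mesenchymal and EMT genes (0.154, 4 of 25 and 6, 0.00263 and 0.506), and immediate early genes (0.0489, 6 of 21 and 8, 0.0356 and 0.59) rose. Hexosamine genes (0.121, 2 of 11 and 2, 0.00359 and 0.293) and fibroblast markers (0.539, 3 of 4 and 3, 0.000352 and 0.293) also rose. Only 4 of the 13 fibroblast markers listed were tested, at any concentration. The mixed list of MondoA targets and starvation regulators (0.237, 4 of 16 and 4, 0.0324 and 0.331) and basal mammary markers (0.131, 5 of 15 and 5, 0.0483 and 0.59) passed with the block only (0.0739 and 0.391 without it). Basal markers did not pass without the 2 libraries with most mitochondrial rRNA (0.184). With a GC and length offset the medians of basal markers (0.0353), YAP targets (0.0973), hexosamine genes (0.0726) and immediate early genes (0.143) moved by over 1.5 times, the last also without the 2 libraries (0.105). Of these rising lists, 1 member each of the transporters, YAP targets, immediate early genes and MondoA targets and 2 basal markers fell over all genes, and 1, 1, 2, 1 and 3 over the list alone. CCNG2, a cyclin of quiescent cells in the list of MondoA targets and starvation regulators, rose by 1.16 (SE 0.127) and the laminin gene LAMA3 by 0.62 (SE 0.101). The members NT5E (0.68, SE 0.0785), CCN2 (0.58, SE 0.121), FN1 (0.51, SE 0.113), DUSP1 (0.44, SE 0.0762) and MT-CYB (0.75, SE 0.105) rose.

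The other lists at 0.04 mM did not pass, with camera adjusted p from 0.101 for glycolysis (median -0.0621) to 0.968 for luminal markers (median -0.0661, mean 0.0268, direction up). They are aminoacyl-tRNA synthetases (-0.00173), glutamine and glutamate enzymes (0.0044, 6 of 30 rose and 6 fell; direction up with the block and down without it), cholesterol synthesis (-0.0776) and fatty acid synthesis (0.0549). They include hypoxia targets (median 0.0763, mean -0.0905, direction up), the citric acid cycle (-0.0991), p53 targets (0.039), and the unfolded protein response (-0.0416). Autophagy and lysosome genes (0.0292), interferon-stimulated genes (0.0615), epidermal differentiation genes (0.162), immune cell markers (0.389, 2 genes), and endothelial markers (0.806, PECAM1 alone of 10 listed) belong here too. PECAM1 as a single gene did rise with the block. The last are programmed cell death genes (median -0.104, mean 0.011, direction up) and polyamine, urea cycle and proline genes (-0.0331). Within them ANGPTL4 (0.58, SE 0.075) and MCL1, which restrains apoptosis (0.46, SE 0.0727), rose. The argininosuccinate lyase gene ASL (-0.59, SE 0.113) and the glutathione synthetase gene GSS (-0.47, SE 0.0879) fell.

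Over all genes at 0.04 mM, 997 rose and 861 fell with the block, 91 of them by at least 2-fold, against 6 and 0 without it (1609 genes at an unadjusted p under 0.05; DESeq2 without the block called 148). DESeq2 with the block called 1549, of which 1492 were among the 1858, and with ERCC scaling 282 rose and 224 fell. Without replicate 2 at 0.04 mM 963 passed, and without replicate 3 in all groups 996. Of the genes that passed with the block, 1064 had no overlap between the groups, which 15.2% of all genes showed. Chance would give 10% with exchangeable libraries, which the shared replicate numbers contradict. At 0.04 against 0.12, 0.12 against 0.20 and 0.04 against 0.28 mM, with few calls, 4.76, 5.18 and 6.03% of all genes had no overlap.

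**Figure D2:**
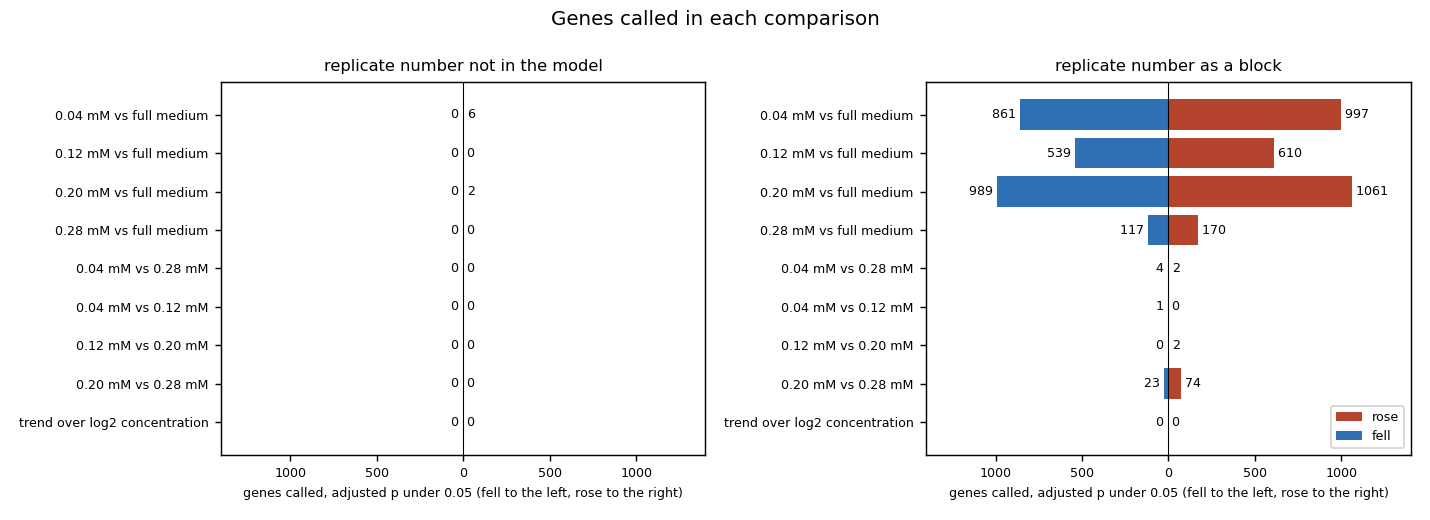
Numbers of genes that rose and fell in each comparison without and with the replicate block, edgeR, adjusted p under 0.05.

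At 0.12 mM, GLUL fell by 0.50 on the log2 scale (SE 0.0713, adjusted p = 5.8e-05), and SLC38A2 (0.57, SE 0.0711, 8.96e-06) and GFPT2 (1.32, SE 0.136, 8.06e-07) rose. TRIB3 (0.26, SE 0.0756, 0.026) and PHGDH (0.35, SE 0.104, 0.03) rose. TRIB3 did not pass without any replicate at 0.12 mM or full medium 2 or 3 (0.21 to 0.28, 0.0549 to 0.131), nor PHGDH without replicate 3 at 0.12 mM (0.24, 0.222) or of full medium (0.17, 0.362). SLC7A11 (0.29, SE 0.108, 0.0984), ATF4 (0.22, SE 0.0822, 0.0893) and TXNIP (0.21, SE 0.0853, 0.127) did not pass. Nor did the other 8 stress genes, from DDIT3 at -0.75 (SE 0.457, 0.344) to CHAC1 at 0.54 (SE 0.588, 0.643). The named genes that rose furthest were HSD17B2 (1.53, SE 0.301), GFPT2, MCF2 (1.17, SE 0.242), FAM167A (1.17, SE 0.22) and SDCBP2, a syntenin (1.09, SE 0.177). Those that fell furthest were EME1 (-1.02, SE 0.196), the antisense GASK1B-AS1 (-0.88, SE 0.196, 26.6% exonic overlap, uncertain) and FUOM, a fucose mutarotase (-0.82, SE 0.23). MMAA (-0.77, SE 0.216) and CHMP6 (-0.74, SE 0.153, 21.5% overlap, uncertain) fell next. FUOM did not pass without 0.12 mM replicate 2 (-0.52, 0.247) or full medium 2 or 3 (-0.78 and -0.79), nor MMAA without 0.12 mM replicate 1 or 3 or full medium 2 or 3 (-0.584 to -0.851, 0.0518 to 0.141). Without the block no gene passed edgeR's test here (1111 genes at an unadjusted p under 0.05, and 23 called by DESeq2). With the block 610 rose and 539 fell (76 and 1130 with ERCC scaling), 53 of them by at least 2-fold. The 1149 became 550 without replicate 2 at 0.12 mM, 744 and 690 without full medium replicates 2 and 3, and 463 without replicate 3 in all groups. DESeq2 called 992, of which 945 were shared. Of the called genes 608 had no overlap between the groups, against 12.2% of all genes and 10% by chance if libraries were exchangeable.

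The lists that fell at 0.12 mM were histones (median -0.351, 30 of 38 fell over all genes and 35 over the list alone, camera adjusted p = 9.4e-31, and 0.293 with an estimated correlation), ribosome biogenesis (-0.151, 12 of 46 and 15, 4.63e-10 and 0.412) and mitochondrial ribosomal proteins (-0.132, 11 of 75 and 18, 5.22e-07 and 0.437). S phase genes (-0.165, 11 of 43 and 17, 2.93e-06 and 0.437), G2 and M phase genes (-0.133, 13 of 53 and 16, 2.92e-05 and 0.497) and proteasome subunits (-0.128, 5 of 32 and 7, 6.75e-05 and 0.437) fell. MYC-linked genes (-0.139, 4 of 22 and 8, 0.000125 and 0.413), nucleotide synthesis (-0.135, 5 of 30 and 7, 0.000696 and 0.413) and snoRNA host genes (-0.146, 2 of 14 and 2, 0.00532 and 0.497; median -0.254 without the 2 libraries with most mitochondrial rRNA) fell too. Over the list alone 1 nucleotide synthesis, 1 MYC-linked and 1 G2 and M phase gene rose. Of their members H2BC9 fell by 0.47 on the log2 scale (SE 0.0716), CDC20 by 0.63 (SE 0.0867) and the mitotic kinase gene AURKB by 0.55 (SE 0.0984). NOP56 fell by 0.38 (SE 0.0677). NRF2 targets (median 0.266, 8 of 25 rose and 12 over the list alone, 1.47e-07 and 0.293), inflammatory genes (0.181, 4 of 22 and 7, 0.000352 and 0.412) and fibroblast markers (0.409, 2 of 4 and 2, 0.000793 and 0.293) rose. ERK output genes (0.132, 7 of 20 and 8, 5.3e-05 and 0.413), mitochondrially encoded mRNAs (0.118, 2 of 13 and 4, 0.00356 and 0.544) and ATF4 genes (0.1, 7 of 41 and 11, 0.00478 and 0.497) rose, with medians of -0.0412, -0.0561 and -0.0883 under scaling to the ERCC spike-ins. Amino acid transporters (0.154, 3 of 26 and 6, 0.00673 and 0.293), hexosamine genes (0.117, 2 of 11 and 2, 0.00852 and 0.293) and YAP targets (0.0836, 2 of 19 and 2, 0.0332 and 0.437) also rose, with medians of -0.0263, -0.0672 and -0.094 under ERCC scaling, which ended all 3 calls (adjusted p = 0.0868, 0.0543 and 0.402). A GC and length offset ended that of the hexosamine genes too (median 0.0395, 0.0506) and left YAP targets at 0.0475. Under that scaling the median change of all genes was -0.177 at 0.12 mM, -0.129 at 0.28 mM, -0.0448 at 0.20 mM and 0.000475 at 0.04 mM. Directions are given relative to the median gene. Of ATF4 genes, transporters and YAP targets 1 each fell over all genes, and 2, 2 and 1 over the list alone. Without the 2 libraries with most mitochondrial rRNA the mitochondrial mRNA median was 0.0709 (0.0342). Of these rising lists, the mitochondrial mRNAs, ATF4 genes, transporters and YAP targets passed with the block only, with adjusted p = 0.0598, 0.121, 0.0773 and 0.0669 without it. Immediate early genes passed only without it (adjusted p = 0.0295, and 0.549 with an estimated correlation; 0.1 with the block).

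No other list passed at 0.12 mM with all libraries (camera adjusted p from 0.0648 to 0.992). Without the 2 libraries with most mitochondrial rRNA, the lists of cytosolic ribosomal proteins (median -0.081, 1 of 77 falling, 1.48e-05), the respiratory chain (-0.049, 0 of 76, 0.0455) and MondoA targets (0.286, 4 of 16 rising and 1 falling, 0.0244) passed camera with the preset correlation. So did, under a GC and length offset, immediate early genes (0.114, 5 rising and 1 falling, 0.00147) and the unfolded protein response (-0.116, 3 falling, 0.0292). Neither setting was run with an estimated correlation. MondoA targets had a median of 0.168, aminoacyl-tRNA synthetases -0.0331, glutamine and glutamate enzymes -0.0297 (mean 0.0353, direction down), cholesterol synthesis -0.0291, and fatty acid synthesis 0.00624 (mean 0.0113, direction down). Glycolysis had -0.0386, hypoxia targets 0.0814, the citric acid cycle -0.023, the nuclear-encoded respiratory chain 0.00778 (mean -0.0101, direction down). Cytosolic ribosomal proteins had 0.00257 (mean 0.00945, direction down), translation factors -0.0666, p53 targets 0.0351, and the unfolded protein response -0.0525. Autophagy genes had 0.0514, interferon-stimulated genes 0.0948, mesenchymal genes 0.0589, epidermal genes 0.0273 (mean -0.048, direction down). Basal markers had 0.021, luminal markers -0.0614 (mean 0.0088, direction up), immune markers 0.228, PECAM1 0.796, cell death genes 0.0261 and polyamine, urea cycle and proline genes -0.0419. As a single gene PECAM1 rose here too with the block. In these lists CCNG2 (0.93, SE 0.126), ANGPTL4 (0.49, SE 0.0739), MCL1 (0.43, SE 0.0726) and LAMA3 (0.40, SE 0.101) rose. The aminoacyl-tRNA synthetase genes VARS1 (-0.34, SE 0.0676) and FARSA (-0.38, SE 0.0773) fell.

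At 0.20 mM, GLUL fell by 0.51 on the log2 scale (SE 0.0709, adjusted p = 2.37e-05). SLC38A2 (0.74, SE 0.071, 7.67e-08), GFPT2 (1.06, SE 0.137, 8.21e-06) and the glutamate dehydrogenase gene GLUD1 (0.29, SE 0.0627, 0.0018) rose. SLITRK6 rose with the block (1.14, SE 0.147, 8.21e-06) and without it (1.15, SE 0.179, 0.043). So did GRAMD1B, a cholesterol transfer protein (2.1 without the block, adjusted p = 0.043, mean 1.941 CPM), which was named after its values were seen. SLC7A11 rose by 0.31 (SE 0.107, 0.0445), but not without any replicate at 0.20 mM or full medium 2 or 3 (0.15 to 0.35, 0.0684 to 0.408). TRIB3 (0.21, SE 0.0752, 0.0596), PHGDH (0.26, SE 0.103, 0.0901), TXNIP (0.21, SE 0.0842, 0.0959), ATF4 (0.19, SE 0.082, 0.115) and the other 8 stress genes, DDIT3 (-0.76, SE 0.445) to CHAC1 (0.31, SE 0.582), did not pass. MCF2 (1.36, SE 0.233), PTCHD4, a p53-induced patched family member (1.19, SE 0.186), LINC02454 (1.18, SE 0.222) and RCBTB2 (1.16, SE 0.292) rose furthest with SLITRK6. PYCR3, a proline synthesis enzyme (-0.76, SE 0.13), FUOM (-0.76, SE 0.223), THOC6 (-0.76, SE 0.158), RELL2 (-0.77, 38.6% overlap) and H3-7 (-0.75, 37.4% overlap) fell furthest, RELL2 and H3-7 being uncertain. Calls ended for FUOM without 0.20 mM replicate 1 or 3 or full medium 2 or 3 (-0.62 to -0.78, 0.0554 to 0.124), H3-7 without full medium 2 (-0.56, 0.0788) and RCBTB2 without 0.20 mM replicate 3 (0.98, 0.067). With the block 1061 genes rose and 989 fell (141 and 280 with ERCC scaling), 73 by at least 2-fold, against 2 and 0 without it (1415 at an unadjusted p under 0.05, and 43 by DESeq2). DESeq2 with the block called 1756, of which 1684 were shared. Of the called genes 1027 had no overlap between the groups (15.5% of all genes, 10% by chance if libraries were exchangeable). Gene GC content correlated with the change at r = -0.352 here, and at -0.157, -0.159 and -0.0867 at 0.04, 0.12 and 0.28 mM. With a GC and length offset 979 genes were called, without replicate 1 or 3 at 0.20 mM 988 and 1131, and without replicate 3 in all groups 985.

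Lists that fell at 0.20 mM were histones (median -0.42, 37 of 38 fell over all genes and 38 over the list alone, camera adjusted p = 1.16e-31, and 0.293 with an estimated correlation), ribosome biogenesis (-0.153, 16 of 46 and 18, 1.51e-06 and 0.437) and cytosolic ribosomal proteins (-0.0895, 13 of 77 and 14, 5.38e-05 and 0.667). Mitochondrial ribosomal proteins (-0.133, 15 of 75 and 18, 0.000209 and 0.506), proteasome subunits (-0.153, 9 of 32 and 12, 0.000716 and 0.497) and S phase genes (-0.126, 12 of 43 and 16, 0.00673 and 0.606) fell. MYC-linked genes (-0.095, 7 of 22 and 9, 0.011 and 0.506) and the respiratory chain (-0.0619, 8 of 76 and 8, 0.0381 and 0.721) fell. Glycolysis (-0.0845, 2 of 23 and 2, 0.0313 and 0.412), the unfolded protein response (-0.069, 7 of 19 and 8, 0.0356 and 0.506) and nucleotide synthesis (-0.129, 6 of 30 and 10, 0.0424 and 0.544) fell with the block only (0.0677, 0.257 and 0.0613 without it). A GC and length offset ended the calls of glycolysis (median -0.0451, 0.49) and the respiratory chain (-0.0553, 0.117). CDC20 (-0.58, SE 0.0859), RFC2, a clamp loader subunit (-0.48, SE 0.0928), SRM (-0.49, SE 0.0664), the chaperone gene CALR (-0.36, SE 0.0769) and NOP56 (-0.43, SE 0.0673) fell. Among G2 and M phase genes, whose list did not pass (median -0.0678, 0.145), 10 genes rose and 14 fell. With a GC and length offset that list passed camera with the preset correlation (median -0.114, 0.000117), with 1 gene rising and 15 falling, and the medians of MYC-linked genes (-0.149), S phase genes (-0.201) and the unfolded protein response (-0.147) moved by over 1.5 times. Against the direction of the falling lists, 2 nucleotide synthesis, 2 respiratory chain, 2 mitochondrial and 1 cytosolic ribosomal protein, 1 MYC-linked, 2 S phase and 1 unfolded protein response gene rose over all genes, and 3, 2, 2, 1, 2, 4 and 2 over the list alone. Inflammatory genes (0.263, 5 of 22 and 6, 0.00101 and 0.413), ERK output genes (0.147, 5 of 20 and 5, 0.00356 and 0.497), hexosamine genes (0.145, 3 of 11 and 5, 0.00673 and 0.293) and MondoA targets (0.21, 3 of 16 and 3, 0.0393 and 0.357) rose in both fits, the last 2 not with a GC and length offset (medians 0.0434 and 0.134, adjusted p = 0.0887 and 0.0506). NRF2 targets (0.127, 7 of 25 and 8, 0.00478 and 0.451), amino acid transporters (0.0674, 6 of 26 and 8, 0.0356 and 0.412) and fibroblast markers (0.361, 2 of 4 and 2, 0.0373 and 0.407) rose with the block only (0.051, 0.186 and 0.17 without it). Of the transporters 2 fell, and of the hexosamine genes 1 over the list alone. CCNG1, a p53-induced cyclin (0.52, SE 0.0798), CCNG2 (0.94, SE 0.124), AREG (0.50, SE 0.075) and NT5E, a nucleotidase (0.61, SE 0.0779), rose.

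Lists that did not pass at 0.20 mM had camera adjusted p from 0.136 to 0.932: ATF4 genes (median 0.0391), aminoacyl-tRNA synthetases (0.0156, mean -0.0301, direction down), glutamine and glutamate enzymes (-0.0825), cholesterol synthesis (-0.0668), and fatty acid synthesis (0.0334, mean -0.00671, direction down). Hypoxia targets (0.0355, mean -0.0382, direction up), the citric acid cycle (-0.104), mitochondrially encoded mRNAs (0.000305), translation factors (-0.0579), and p53 targets (0.0251) did not pass. Nor did autophagy genes (0.0498), interferon-stimulated genes (0.155), immediate early genes (-0.0124, mean 0.0425, direction up), YAP targets (0.0717) and mesenchymal genes (0.0322). The others were epidermal genes (-0.221), basal markers (-0.0308), luminal markers (-0.175), immune markers (-0.0267) and the list of PECAM1 alone (0.85, which rose as a single gene with a GC and length offset). Cell death genes (0.0241), polyamine, urea cycle and proline genes (0.00386, mean -0.0308, direction down) and snoRNA host genes (-0.088) complete them. ATF4 genes with a GC and length offset (median 0.0562, 7 of 41 rising, 0.00384), immediate early genes (0.0873, 6 rising and 1 falling, 0.00805), YAP targets (0.0243, 2 of 19 rising, 0.0343) and translation factors (-0.102, 4 falling and 1 rising, 0.00918) passed with the preset correlation. An estimated one was not run in that setting. The stress regulator ZFP36 (-0.55, SE 0.0873) and ASL (-0.67, SE 0.107) fell. The antizyme inhibitor gene AZIN1 (0.52, SE 0.0793), MCL1 (0.43, SE 0.0726) and EIF3E, an initiation factor subunit (0.46, SE 0.074), rose.

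At 0.28 mM, GLUL fell by 0.43 on the log2 scale (SE 0.0708, adjusted p = 0.000952). SLC38A2 (0.37, SE 0.0709, 0.00552), GFPT2 (1.04, SE 0.137, 0.000196) and TRIB3 (0.27, SE 0.0751, 0.0491) rose. SLC38A2 did not pass without 0.28 mM replicate 1 or 3 or full medium 2 (0.33 to 0.35, 0.0507 to 0.1), nor TRIB3 without either of these replicates or full medium 2 or 3 (0.18 to 0.26, 0.171 to 0.434). PHGDH (0.32, SE 0.103, 0.0908), SLC7A11 (0.24, SE 0.107, 0.253), ATF4 (0.18, SE 0.0821, 0.265), TXNIP (0.18, SE 0.0845, 0.297) and the other 8 stress genes, DDIT3 (-0.28, SE 0.425) to CHAC1 (0.83, SE 0.558), did not pass. MCF2 (1.22, SE 0.237), GFPT2, PTCHD4 (0.95, SE 0.19), SDCBP2 (0.91, SE 0.177) and MT-ATP8 (0.81, SE 0.195, 22.2% overlap with MT-ATP6 and so uncertain) rose furthest. MPND (-0.73, SE 0.201, 23.2% overlap, uncertain), THOC6 (-0.66, SE 0.157), the histone gene H4C1 (-0.57, SE 0.135), PYCR3 (-0.56, SE 0.129) and JMJD4 (-0.60, 53.8% overlap, uncertain) fell furthest. Of these 10 genes only GFPT2 and JMJD4 passed with each single library left out. The others failed without 1 or more of the 0.28 mM libraries and full medium 2 and 3 (adjusted p up to 0.272), and without full medium 3 MT-ATP8 was 0.51, without replicate 3 at 0.28 mM PYCR3 -0.37. With the block 170 genes rose and 117 fell (18 and 102 with ERCC scaling), 10 by at least 2-fold. This count of 287 became 32 and 24 without replicates 1 and 3 at 0.28 mM, 775, 60 and 69 without full medium replicates 1, 2 and 3, and 1 without replicate 3 in all groups. None passed without it (616 at an unadjusted p under 0.05, and 1 by DESeq2). DESeq2 with the block called 316, of which 241 were shared. Of the called genes 160 had no overlap between the groups, where 9.29% of all genes had none. Chance gives 10% only if libraries are exchangeable, and the comparisons with few calls named above had 4.76 to 6.03%.

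Histones fell at 0.28 mM (median -0.282, 19 of 38 over all genes and 37 over the list alone, camera adjusted p = 1.73e-31, and 0.293 with an estimated correlation), with H2BC9 at -0.43 (SE 0.0707). Ribosome biogenesis (-0.106, 4 of 46 and 10, 7.11e-08 and 0.413), mitochondrial ribosomal proteins (-0.119, 1 of 75 and 1, 1.9e-07 and 0.434) and S phase genes (-0.141, 3 of 43 and 13, 1.92e-06 and 0.437) fell. Nucleotide synthesis (-0.097, 1 of 30 and 5, 0.00123 and 0.413), MYC-linked genes (-0.0831, 1 of 22 and 3, 0.00131 and 0.437) and proteasome subunits (-0.0736, 1 of 32 and 1, 0.00135 and 0.506) fell too. G2 and M phase genes (-0.0556, 4 of 53 and 11, 0.00291 and 0.59) also fell, and snoRNA host genes passed as a list (-0.123, 0.00715 and 0.506) with 0 of 14 falling over all genes and 1 over the list alone. Mitochondrially encoded mRNAs (0.224, 3 of 13 rose and 4 over the list alone, 1.63e-07 and 0.413) and ERK output genes (0.143, 4 of 20 and 7, 6.47e-06 and 0.412) rose. Inflammatory genes (0.2, 1 of 22 and 1, 0.000129 and 0.412) and fibroblast markers (0.23, 1 of 4 and 1, 0.0231 and 0.357) rose. Relative to the median gene, NRF2 targets (0.123, 2 of 25 and 5, 0.000129 and 0.412), ATF4 genes (0.117, 2 of 41 and 5, 0.000137 and 0.434) and YAP targets (0.126, 2 of 19 and 3, 0.000363 and 0.357) rose, with medians of -0.00682, -0.00843 and -0.00296 under ERCC scaling. Amino acid transporters (0.119, 2 of 26 and 2, 0.00164 and 0.293) rose, with -0.00573 under that scaling. Mesenchymal genes passed as a list (0.11, 0.00152 and 0.506, and -0.016 under that scaling), but 0 of 25 rose over all genes or over the list alone. Hexosamine genes (0.101, 1 of 11 and 2, 0.00558 and 0.293) and MondoA targets (0.109, 2 of 16 and 3, with 1 falling over the list alone, 0.0483 and 0.357) rose, with -0.0334 and -0.0214 under it. Of all these, fibroblast markers and MondoA targets passed with the block only (0.262 and 0.0773 without it), and MondoA targets not with a GC and length offset (0.0523) or DESeq2 size factors (0.0508). With that offset the medians of YAP targets and hexosamine genes were 0.0809 and 0.0572. Named members were AKR1C1 (0.53, SE 0.105), CCNG2 (0.67, SE 0.126), NT5E (0.46, SE 0.0779), AREG (0.36, SE 0.0749), SRM (-0.30, SE 0.0661) and CDC20 (-0.39, SE 0.0856).

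**Figure D3:**
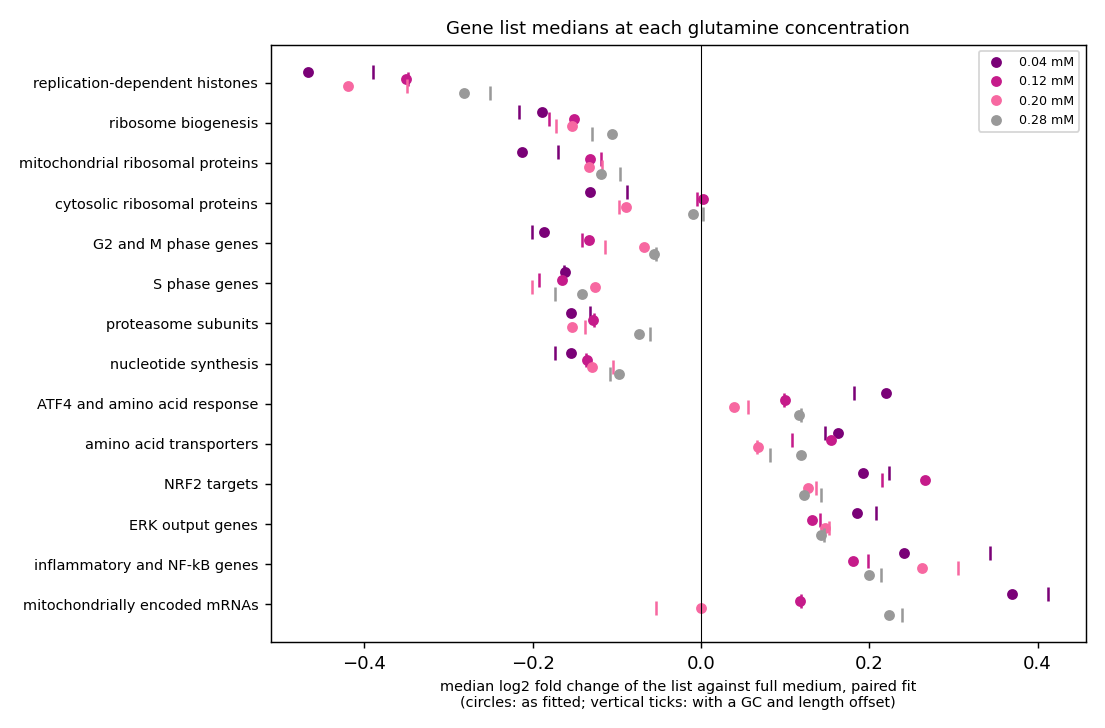
Median log2 change of 14 of the 42 gene lists at each limited concentration against full medium, with ticks for the values under a GC and length offset. The 14 lists were picked after their values were seen, and under ERCC scaling several of the rising medians turn negative at 0.12 and 0.28 mM.

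Lists that did not pass at 0.28 mM had adjusted p from 0.0542 to 0.919: immediate early genes (median 0.107, but 0.152 and adjusted p = 0.0018 with a GC and length offset), aminoacyl-tRNA synthetases (0.0194, mean -0.013, direction down), glutamine and glutamate enzymes (-0.0575, mean 0.021, direction down), cholesterol synthesis (-0.022), fatty acid synthesis (0.0123) and glycolysis (-0.00337). Hypoxia targets (0.00361, mean -0.0445, direction up with the block and down without it), the citric acid cycle (-0.0344), the respiratory chain (-0.00298), cytosolic ribosomal proteins (-0.00974, mean 0.00093, direction down), translation factors (-0.069) and p53 targets (0.0168) did not pass. Nor did the unfolded protein response (-0.0418), autophagy genes (0.0821), interferon-stimulated genes (0.0507), epidermal genes (0.0254, mean -0.0509, direction down). Basal markers (0.0174), luminal markers (0.00321), immune markers (0.09), PECAM1 (0.429), cell death genes (-0.0113, mean 0.0126, direction up) and polyamine, urea cycle and proline genes (0.0108, mean -0.00457, direction down) complete them. In these lists MCL1 (0.41, SE 0.0725), the lysosomal cholesterol exporter gene NPC1 (0.26, SE 0.0707) and ANGPTL4 (0.34, SE 0.0735) rose. KRT16, a keratin of activated epidermis (-0.32, SE 0.0782), fell. In total 81 of the 168 list tests passed with the block and 68 without it, 67 of them shared. With an estimated correlation 0 passed in either fit, and the directional fry test called 28 and 2 of these.

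Across the 4 concentrations the changes shared direction. Of the genes that passed with the block at 0.04 mM, 499 rose and 428 fell also at 0.12 mM (44 and 33.6 by chance), 604 and 600 at 0.20 mM (76.5 and 61.6 by chance) and 156 and 108 at 0.28 mM (12.3 and 7.29 by chance). The remaining pairs shared 440 and 445 (0.12 and 0.20 mM; 46.8 and 38.6 by chance), 155 and 106 (0.12 and 0.28 mM; 7.5 and 4.56) and 134 and 110 (0.20 and 0.28 mM; 13 and 8.37). In opposite directions, 0 genes passed. GLUL, SLC38A2, GFPT2, AREG, NT5E, CCNG2, AKR1C1, SRM, CDC20 and H2BC9 passed at all 4. The correlations of log2 changes were 0.621 to 0.722. All 4 comparisons use the same 3 full-medium libraries, so the counts by chance, which treat the comparisons as independent, are too low a baseline. In 20 simulations of unchanged groups the mean correlations were 0.471 to 0.511, with at most 1 shared gene. Each gene was drawn on its own and unchanged there, so few calls, and few shared ones, follow by construction. Deviations common to many genes of a library were not simulated. The 3 controls cannot be divided with at least 2 for each comparison, so how much of the excess comes from them is not known.

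Between limited concentrations the fit of all 15 libraries called fewer genes than against full medium. At 0.20 against 0.28 mM, 74 genes were higher and 23 lower with the block, among them SLITRK6 (0.60, SE 0.139, adjusted p = 0.0402), and ASNSD1 (0.57, SE 0.138, 0.0442). PIK3C2G, a lipid kinase (0.54, SE 0.122, 0.036), CMTR2, an mRNA cap methyltransferase (0.53, SE 0.116, 0.0273), and KIF18A, a mitotic kinesin (0.46, SE 0.112, 0.0442), were higher too. RPL26, a ribosomal protein gene with many pseudogenes, was lower (-0.90, SE 0.163, 0.00963). VIM-AS1 (-1.5, SE 0.287, 0.00994), ALDOA (-0.95, SE 0.228, 0.0441) and DDT (-0.85, SE 0.207, 0.0442) were lower as well but share 32.2, 53.5 and 37.8% of their exons with other genes, so these 3 are uncertain. Of the 97 genes, 26 had no overlap between the groups (7.68% of all genes, 10% by chance). With a GC and length offset 1 gene was higher and 8 lower, and GC content correlated with this change at r = -0.34. Leaving out 1 library left 3 (0.28 mM, replicate 2) to 25 genes (0.20 mM, replicate 2), while a fit of these 2 groups alone called 1431 (784 higher and 647 lower), and none passed without the block (295 at an unadjusted p under 0.05). At 0.04 against 0.28 mM 2 genes were higher, BIRC3 (0.58, SE 0.101, 0.0142) and ATRX (0.39, SE 0.0752, 0.0384). Both calls ended with a GC offset, alone or with length, and 2 lower genes passed. The 4 lower ones were RPL26 (-0.96, SE 0.171, 0.0164), RPS26 (-0.51, SE 0.101, 0.0498), TMA7 (-0.50, SE 0.101, 0.0499, 53.2% overlap and so uncertain) and ENSG00000276700 (-0.79, SE 0.093, 1.71e-05). At 0.04 against 0.12 mM ENSG00000276700 was lower (-0.65, SE 0.0937, 0.00115). At 0.12 against 0.20 mM it was higher (0.75, SE 0.0918, 4.13e-05) with ENSG00000289252 (1.52, SE 0.253, 0.00805). In these 3 comparisons all genes except TMA7 were named after their values were seen. Without the block none passed (284, 190 and 146 genes at an unadjusted p under 0.05).

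No gene followed a trend over log2 concentration within the 12 limited libraries, without the block (306 at an unadjusted p under 0.05) or with it (1063), while 28 passed with the block and a GC and length offset. In order of rising concentration, GLUL had log2 changes of -0.58, -0.50, -0.51 and -0.43 and the histone list medians were -0.467, -0.351, -0.42 and -0.282. Differences of a list between concentrations were not tested.

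Mitochondrial ribosomal RNA was uneven among libraries, from 0.000974% of gene counts (0.28 mM, replicate 2) to 2.97% (0.04 mM, replicate 3), with 1.62% in replicate 3 at 0.12 mM and 0.402% in replicate 1 at 0.20 mM. Mitochondrial mRNAs took 0.865 to 1.86%. Without the 2 libraries above 1%, 1438 genes passed with the block at 0.04 mM, 873 at 0.12 mM, 2135 at 0.20 mM and 338 at 0.28 mM, and 80 of the 81 list calls held. PHGDH no longer passed at 0.04 mM (0.23, adjusted p = 0.146).

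**Figure D4:**
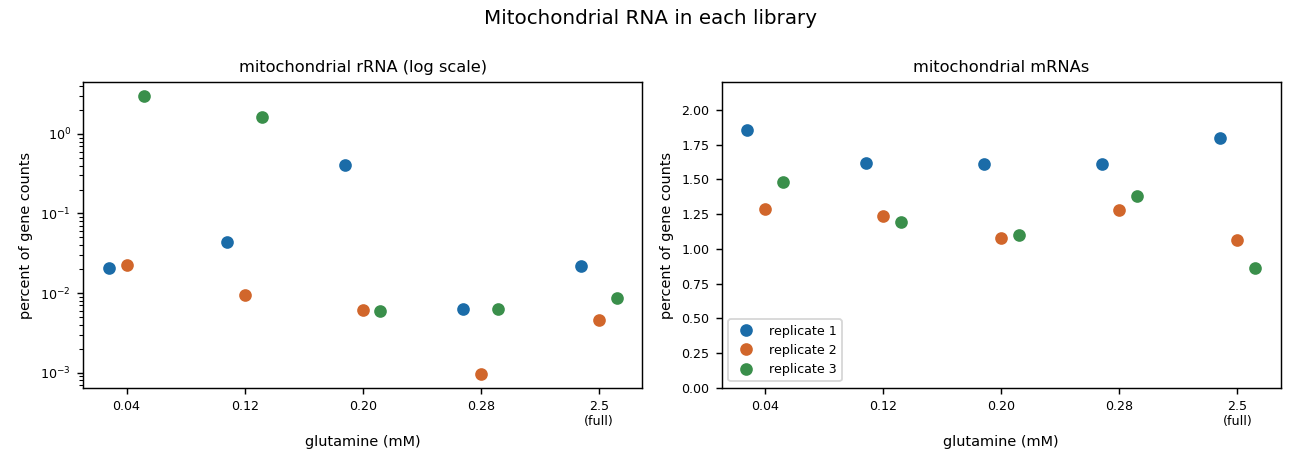
Share of gene counts in mitochondrial ribosomal RNA (logarithmic axis) and in mitochondrially encoded mRNAs in each of the 15 libraries.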

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

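Chosen after the data were seen were the settings at equal depth, with a GC offset, with a GC and length offset, without the 2 libraries with high mitochondrial rRNA and without the third replicates, and for the GC offset and both tests of mitochondrial RNA the bound was also set after the value was seen.

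The genes that follow stood out because their changes against full medium differed between 2 limited concentrations when that difference itself was tested, in the fit with the replicate block. At 0.04 against 0.28 mM TMA7 differed by -0.50 (uncertain, with 53.2% of its exons shared), and it did not pass without 0.04 mM replicate 2 or 3 or any replicate at 0.28 mM (edgeR adjusted p from 0.0825 to 0.514). At 0.20 against 0.28 mM SLITRK6 differed by 0.60 and passed, of the 6 libraries left out in turn, only without 0.20 mM replicate 2 (otherwise 0.108 to 0.295). ASNSD1 (0.57, then 0.0908 to 0.296), PIK3C2G (0.54, then 0.0962 to 0.262) and KIF18A (0.46, then 0.112 to 0.302) passed with none of the 6 left out. CMTR2 differed by 0.53 and passed only without 0.28 mM replicate 1 (otherwise 0.0709 to 0.31). VIM-AS1 (-1.5, 32.2% of exons shared) did not pass without 0.20 mM replicate 1 or 3 or 0.28 mM replicate 2 (0.0989 to 0.198). ALDOA (-0.95, 53.5% shared) passed with none of the 6 left out (0.0551 to 0.491) and was -0.60 without 0.20 mM replicate 1. RPL26 (-0.90) did not pass without 0.20 mM replicate 1 (0.113) or 0.28 mM replicate 2 (0.178). DDT (-0.85, 37.8% shared) passed with none left out (0.0891 to 0.344). With a GC and length offset VIM-AS1 and RPL26 of these 10 still passed.

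With the block, 2050 genes passed at 0.20 mM and 1858 at 0.04 mM, although 0.04 mM is the stronger limitation. At equal depth the count at 0.20 mM was 0.909 times that at 0.04 mM, with a GC offset 0.554 times and without the third replicates 0.989 times, so library depth, a GC trend between libraries and the third replicates each stay open as candidate explanations. Without the 2 libraries with high mitochondrial rRNA the ratio was 1.48, which meets the bound set beforehand against those libraries as the cause. That bound was wrong for this design, because 0.04 mM then keeps 2 libraries against 3 at 0.20 mM, so the effect of these 2 libraries cannot be told apart from that of the group size. No biological explanation was tested.

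Mitochondrial rRNA took a share of counts that spanned 3050 times over the 15 libraries, highest in replicate 3 at 0.04 mM (2.97%) and at 0.12 mM (1.62%). More mitochondrial RNA in those cells would raise the mitochondrial mRNAs too, but their share spanned only 2.15 times, which argues against it. Uneven depletion of ribosomal RNA between libraries, which predicts a wide span of the rRNA alone, stays open as a candidate explanation, and changes of MT-RNR2 may follow it.

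The libraries were also divided in other ways. Without the block the 6 libraries of a comparison make 10 splits, too few for a share under 0.05. The real split called 6 genes at 0.04 mM and 2 at 0.20 mM, where it was the 1 split of 10 with as many, and the highest other split called 0. In the remaining comparisons real and highest other were both 0, in all 10 splits. With the block, 4 splits part the 3 same-number pairs, again too few. Real and highest other counts were 1858 and 0 at 0.04 mM, 1149 and 0 at 0.12 mM, 2050 and 0 at 0.20 mM and 287 and 1 at 0.28 mM. Between limited concentrations they were 6 and 0 (0.04 against 0.28 mM), 1 and 0 (0.04 against 0.12), 2 and 1 (0.12 against 0.20) and 97 and 0 (0.20 against 0.28). Splits that part 1 pair and leave 2 pairs together rest on another contrast and are not compared with the real split. They called up to 40 genes at 0.04 against 0.12 mM, 22 at 0.28 mM, 5 at 0.12 against 0.20 mM, 3 at 0.20 against 0.28 mM, 1 at each other concentration against full medium and 0 at 0.04 against 0.28 mM.

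For the trend over concentration the real order of the 12 limited libraries called 0 genes with and without the block, so all 100 of 100 orders call at least as many by construction, and their number says nothing about chance. The highest other orders called 1538, 1241, 1024 and 3 genes without the block, and the highest 111 with it. Whether the first 3 follow the replicate numbers, which dominate components 1 and 2, was not traced.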

How the results depend on the processing

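Chosen after the data were seen were every further alternative combined with the replicate block, among them the thinning to equal depth, the GC and length offsets, leaving out the 2 libraries with high mitochondrial rRNA and leaving out replicate 3. Where no cause is given for a changed value, the cause was not tested. Depth limits the weak genes: ASNS (a mean of at most 1.49 CPM in a group), CHAC1 and DDIT3 stand on few counts, and ASNS (44.6%), DDIT3 (39.6%) and SLC1A5 (23.8%) share exons with other genes, and the shallowest library (0.04 mM, replicate 3) holds 3704170 counts. No named gene that passed in a fit, with or without the block, changed direction under the alternatives to that fit, and over all called genes those with the opposite sign were, with the block, 2 with a GC offset and 5 with a GC and length offset at 0.20 mM, and 1 without replicate 3 and 1 without the 2 libraries at 0.04 mM, with 0 of these passing in the new direction. For 15 values of called genes DESeq2 gave no adjusted p, and these were left out. A library left out leaves 2 in its group, and the fit shares the spread over all groups.

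The replicate block, an alternative planned before the data were examined, raised the counts of called genes from 6, 0, 2 and 0 to 1858, 1149, 2050 and 287 from the lowest to the highest limited concentration. Between limited concentrations it raised them from 0 to 6 (0.04 against 0.28 mM), 1 (0.04 against 0.12), 2 (0.12 against 0.20) and 97 (0.20 against 0.28). By construction, the block removes differences between replicate numbers from the spread. It kept all 6 and 2 unblocked calls, and the trend stayed at 0. Of 68 unblocked list calls it kept 67.

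Without the block, DESeq2 called 148, 23, 43 and 1 genes in the 4 comparisons with full medium, in order of rising concentration, and DESeq2 size factors in edgeR 10 at 0.04 mM. ERCC scaling and fits of the 2 compared groups alone left 0 at 0.04 and 0 at 0.20 mM, and the filter of 5 CPM in 3 libraries left 2 and 0. With no filter 159, 58, 84 and 19 passed against full medium, and 7 (0.04 against 0.28 mM), 4 (0.04 against 0.12), 7 (0.12 against 0.20) and 12 (0.20 against 0.28) between limited concentrations. A trend over all 15 libraries, full medium included, called 157. Directions of genes that never passed turned under ERCC scaling for SESN2 (-0.21), PSAT1 (-0.14), SLC1A5 (-0.15) and CDKN1A (-0.16) at 0.12 mM and SESN2 (-0.00852) and CDKN1A (-0.0893) at 0.28 mM. SESN2 at 0.12 mM also turned with no filter (-0.00966) and with 2 groups alone (-0.00242). ERCC scaling shifts every gene of a comparison alike.

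With the block, DESeq2 called 43 genes at 0.04 against 0.28 mM, 2 at 0.04 against 0.12 mM and 24 for the trend, and CHAC1 turned at 0.20 mM (-0.11). ERCC scaling left 506, 421 and 120 at 0.04, 0.20 and 0.28 mM and 22 at 0.20 against 0.28 mM, and turned SESN2 (-0.17), PSAT1 (-0.16), SLC1A5 (-0.13) and CDKN1A (-0.14) at 0.12 mM and SESN2 (-0.0213), PSAT1 (-0.0762) and CDKN1A (-0.0668) at 0.28 mM. No filter gave 63, 23, 12 and 180 for 0.04 against 0.28, 0.04 against 0.12, 0.12 against 0.20 and 0.20 against 0.28 mM, and 34 for the trend, with SESN2 at -0.000425 at 0.12 mM. Fits of 2 groups alone, in which fewer samples set the spread, gave 1189 at 0.04 and 296 at 0.12 mM, and 78, 2, 11 and 1431 in the same order of limited comparisons, with SESN2 at -0.00433. The trend over all 15 libraries called 2163.

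At equal depth 713, 1230 and 147 genes passed at 0.12 mM, at 0.20 mM and at 0.28 mM, 2 at 0.04 against 0.12 mM, 1 at 0.12 against 0.20 mM and 39 at 0.20 against 0.28 mM, and PSAT1 turned at 0.12 mM (-0.043). A GC offset left 881 at 0.20 mM, 2 at 0.04 against 0.28 mM and 8 at 0.20 against 0.28 mM, with 3 for the trend. It turned PSAT1 at 0.12 mM (-0.0385) and SESN2 (0.0698), PSAT1 (-0.0401), SLC1A5 (0.0891) and CDKN1A (0.0538) at 0.20 mM. A length offset gave 10 at 0.04 against 0.28 mM, 2 at 0.04 against 0.12 mM and 149 at 0.20 against 0.28 mM. Both together left 979 at 0.20 mM, 2 at 0.04 against 0.28 mM and 9 at 0.20 against 0.28 mM, with 28 for the trend. They turned MYC at 0.04 mM (0.00422), PSAT1 at 0.12 mM (-0.00181) and SESN2 (0.0638), PSAT1 (-0.0134), SLC1A5 (0.091) and CDKN1A (0.0667) at 0.20 mM.

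Without replicate 3 in all groups, 996, 463, 985 and 1 genes passed against full medium, and 3 (0.04 against 0.28 mM), 0 (0.04 against 0.12), 1 (0.12 against 0.20) and 9 (0.20 against 0.28) otherwise. This setting has fewer samples by construction. ASNS (-0.32), DDIT3 (-0.58), PSAT1 (-0.0185) and CDKN1A (-0.0109) turned at 0.04 mM, and ASNS (-0.0451), CHAC1 (-0.1), PSAT1 (-0.0697) and CDKN1A (-0.00147) at 0.12 mM. CHAC1 (-1.03) and PSAT1 (-0.0498) turned at 0.20 mM, and ASNS (-0.497), CHAC1 (-0.31) and PSAT1 (-0.097) at 0.28 mM. Without the 2 libraries with high mitochondrial rRNA, 0 passed at 0.04 against 0.12 mM and 1 at 0.12 against 0.20 mM, and DDIT3 turned at 0.04 mM (-0.52).

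Single libraries moved the counts. Without the block, the 6 calls at 0.04 mM became 3 without replicate 1 of that group, 41 without full medium replicate 1, and 0 without replicate 2 or 3 of either group. The 2 calls at 0.20 mM became 0 without any of its own replicates or full medium replicates 2 or 3 and stayed 2 without full medium replicate 1. At 0.12 mM 2 passed without its replicate 1 and 5 without full medium replicate 1, and 0 otherwise. With the block the count at 0.04 mM ran from 963 (its replicate 2 out) to 2088 (full medium 1 out). At 0.12 mM it ran from 550 (its replicate 2) to 1438 (full medium 1). At 0.20 mM it ran from 988 (its replicate 1) to 1880 (full medium 1), and at 0.28 mM from 24 to 775. At 0.20 against 0.28 mM it was 9, 25 and 11 without replicates 1, 2 and 3 at 0.20 mM, and 24, 3 and 11 without those at 0.28 mM. At 0.04 against 0.28 mM it was 16, 1 and 3, and 3, 1 and 3. At 0.04 against 0.12 mM it ran from 0 (0.12 mM 1 or 0.04 mM 3) to 42 (0.12 mM 2), with 2 without 0.04 mM 2. At 0.12 against 0.20 mM it was 1 without replicate 1 or 3 of either group and 26 without 0.12 mM 2. The trend ran from 0 to 3 (0.28 mM 1).

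With the block, GLUL at all 4 concentrations, and SLC38A2 at all except 0.28 mM, passed with each single library left out. Over all named genes, 139 values with the block and 22 without it fell short when a single library was left out, and 583 and 694 were the same.

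Without the block, genes that did not pass turned as follows, lowest to highest with the library left out. At 0.04 mM the range was ASNS -0.19 (0.04 mM 3) to 1.41 (0.04 mM 1), DDIT3 -0.31 (0.04 mM 3) to 0.67 (full medium 2) and PSAT1 -0.14 (0.04 mM 3) to 0.42 (0.04 mM 1). PHGDH -0.0784 (0.04 mM 3) to 0.82 (0.04 mM 1), MYC -0.13 (0.04 mM 1) to 0.00688 (full medium 1) and CDKN1A -0.20 (full medium 3) to 0.42 (full medium 1). At 0.12 mM the range was SESN2 -0.0986 (0.12 mM 1) to 0.0869 (0.12 mM 3), PSAT1 -0.20 (0.12 mM 3) to 0.21 (0.12 mM 1) and PHGDH -0.11 (0.12 mM 3) to 0.73 (0.12 mM 1). SLC1A5 -0.0148 (0.12 mM 1) to 0.11 (full medium 1), MYC -0.12 (full medium 2) to 0.0202 (full medium 1) and CDKN1A -0.29 (0.12 mM 1) to 0.39 (full medium 1). At 0.20 mM the range was CHAC1 -0.84 (0.20 mM 3) to 1.34 (0.20 mM 1), SESN2 -0.0986 (full medium 2) to 0.0139 (full medium 1) and PSAT1 -0.19 (0.20 mM 3) to 0.28 (0.20 mM 1). PHGDH -0.0766 (0.20 mM 3) to 0.53 (full medium 3), SLC1A5 -0.0755 (full medium 2) to 0.0231 (full medium 1) and CDKN1A -0.33 (0.20 mM 1) to 0.29 (full medium 1). At 0.28 mM the range was ASNS -0.39 (0.28 mM 3) to 0.67 (0.28 mM 2), DDIT3 -0.81 (0.28 mM 1) to 0.13 (full medium 2) and CHAC1 -0.18 (0.28 mM 3) to 1.77 (0.28 mM 1). PSAT1 -0.22 (0.28 mM 3) to 0.25 (0.28 mM 1), PHGDH -0.0634 (0.28 mM 3) to 0.64 (0.28 mM 1) and TXNIP -0.025 (full medium 3) to 0.34 (0.28 mM 3). MYC -0.12 (full medium 2) to 0.0142 (full medium 1) and CDKN1A -0.23 (0.28 mM 1) to 0.40 (full medium 1).

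With the block, the same was seen for these genes. At 0.04 mM the range was ASNS -0.0583 (full medium 3) to 1.41 (full medium 1) and DDIT3 -0.47 (0.04 mM 3) to 0.71 (full medium 2). At 0.12 mM the range was ASNS -0.23 (full medium 3) to 1.21 (full medium 1), CHAC1 -0.43 (full medium 3) to 1.68 (full medium 1) and SESN2 -0.0887 (0.12 mM 1) to 0.0937 (0.12 mM 3). PSAT1 -0.11 (full medium 3) to 0.15 (full medium 1) and CDKN1A -0.0191 (full medium 3) to 0.12 (full medium 1). At 0.20 mM the range was ASNS -1.42 (full medium 3) to 0.0707 (full medium 1), CHAC1 -0.72 (full medium 3) to 1.42 (full medium 1) and SESN2 -0.10 (full medium 2) to 0.0028 (full medium 1). PSAT1 -0.0708 (full medium 3) to 0.19 (full medium 1) and CDKN1A -0.11 (full medium 3) to 0.0288 (full medium 1). At 0.28 mM the range was ASNS -0.60 (full medium 3) to 0.89 (full medium 1), DDIT3 -0.89 (0.28 mM 1) to 0.22 (full medium 2) and CHAC1 -0.19 (full medium 3) to 1.97 (full medium 1). PSAT1 -0.0949 (full medium 3) to 0.17 (full medium 1).

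Of the list calls with the block, 78 of 81 held under ERCC scaling, 80 with DESeq2 size factors, 74 with a GC and length offset, 80 without the 2 libraries with high mitochondrial rRNA and 28 under fry, and 0 with an estimated correlation. Lost under ERCC scaling, all at 0.12 mM, were amino acid transporters (camera adjusted p = 0.0868), YAP targets (0.402) and hexosamine genes (0.0543). The GC and length offset ended glycolysis (0.49), the respiratory chain (0.117), MondoA targets (0.0506) and hexosamine genes (0.0887) at 0.20 mM, snoRNA host genes at 0.04 mM (0.0523), hexosamine genes at 0.12 mM (0.0506) and MondoA targets at 0.28 mM (0.0523). Size factors ended MondoA targets at 0.28 mM (0.0508), and leaving out the 2 libraries ended basal markers at 0.04 mM (0.184).

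Other lists gained a call. The GC and length offset added the unfolded protein response at 0.12 mM (0.0292), immediate early genes at 0.12 (0.00147), 0.20 (0.00805) and 0.28 mM (0.0018), and at 0.20 mM ATF4 genes (0.00384), translation factors (0.00918), G2 and M phase genes (0.000117) and YAP targets (0.0343). Leaving out the 2 libraries added at 0.12 mM cytosolic ribosomal proteins (1.48e-05), the respiratory chain (0.0455) and MondoA targets (0.0244), and at 0.28 mM immediate early genes (0.0461). ERCC scaling added at 0.12 mM aminoacyl-tRNA synthetases (0.0155), glycolysis (0.0349), cytosolic ribosomal proteins (0.0104), translation factors (0.00246), MondoA targets (0.0231), the unfolded protein response (0.0164), interferon-stimulated genes (0.022) and PECAM1 (0.0408). It also added PECAM1 at 0.20 mM (0.0477), and cytosolic ribosomal proteins (0.03) and translation factors (0.00647) at 0.28 mM. For PECAM1 these are tests of its list, not of the single gene.

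Medians of lists that kept their call moved by over 1.5 times in 3 settings. ERCC scaling, which shifts all genes of a comparison alike, moved most of them at 0.12 and 0.28 mM and some at 0.20 mM, for example inflammatory genes at 0.12 mM to 0.0051 (from 0.181), ERK output genes at 0.28 mM to 0.018 (from 0.143) and mitochondrial ribosomal proteins to -0.321 (from -0.132) and -0.258 (from -0.119) at 0.12 and 0.28 mM. Under the GC and length offset the 0.04 mM medians became 0.143 for immediate early genes (from 0.0489), 0.0973 for YAP targets (from 0.154), 0.0353 for basal markers (from 0.131) and 0.0726 for hexosamine genes (from 0.121). At 0.12 mM YAP targets became 0.0475 (from 0.0836). MYC-linked genes at 0.20 mM became -0.149 (from -0.095), S phase genes -0.201 (from -0.126) and the unfolded protein response -0.147 (from -0.069). At 0.28 mM YAP targets became 0.0809 (from 0.126) and hexosamine genes 0.0572 (from 0.101). Without the 2 libraries ATF4 genes at 0.04 mM became 0.133 (from 0.22) and immediate early genes there 0.105 (from 0.0489), and at 0.12 mM mitochondrial mRNAs 0.0709 (from 0.118) and snoRNA host genes -0.254 (from -0.146).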

Other observations

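The test of S phase genes against the histone pattern was chosen after its values were seen, the GC and length offset used in it was added after the data were seen, and the genes in the next paragraph were picked after their values were seen.

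The 11 genes given here passed at all 4 limited concentrations in the fit with the block, and their values run from the lowest to the highest concentration. They form no tested group. KYNU, an enzyme of tryptophan breakdown, rose by 0.84, 0.70, 0.74 and 0.51 (edgeR adjusted p at most 0.000381). ANTXR2, a receptor for anthrax toxin and collagen, had 0.89, 0.80, 0.70 and 0.63 (at most 3e-04), and SMOC1, a calcium-binding matrix protein, 0.92, 0.80, 0.67 and 0.69 (at most 0.000349). IL31RA, a cytokine receptor subunit, had 0.63, 0.60, 0.58 and 0.61 (at most 3e-04), and OSMR, its partner in the interleukin 31 receptor, 0.41, 0.35, 0.32 and 0.31 (at most 0.0156). The acetylcholine receptor gene CHRNA9 rose by 0.91, 0.87, 0.64 and 0.57 (at most 0.00313), the potassium channel gene KCNJ15 by 0.89, 0.80, 0.65 and 0.61 (at most 0.0151) and the integrin gene ITGB2 by 1.16, 0.98, 0.88 and 0.79 (at most 0.0144). MXD4, which opposes MYC at its binding sites, rose by 0.58, 0.63, 0.37 and 0.45 (at most 0.00599). SLC25A11, which carries oxoglutarate across the inner mitochondrial membrane, had -0.46, -0.44, -0.44 and -0.41 (at most 0.00366), and the DNA ligase gene LIG1 -0.47, -0.50, -0.49 and -0.35 (at most 0.0139). Without the block none of these 11 genes passed.

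Replication-dependent histone mRNAs were lower at all 4 concentrations, each compared with the same 3 full-medium libraries. With an offset for GC and length the median at 0.04 mM stayed at -0.39 with 38 of 38 members negative, which argues against a GC and length trend between libraries as the whole cause. Nor does 1 library decide it at 0.04 mM, where over the 6 fits that leave out 1 library the highest median was -0.437, and the other 3 concentrations were not run. Fewer cells in S phase may account for it: with the offset the S phase genes also had negative medians at all 4 concentrations, the highest being -0.163. The number of cells in S phase was not measured, the loss of call with an estimated correlation (adjusted p = 0.293) applies here as well, and this stays a hypothesis found and tested on the same data.

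Of the variance of components 1, 2 and 3 of log2 CPM, 88.7, 80.3 and 8.31% lay between replicate numbers. Groups held 9.57, 9.33 and 71.8%. What the replicate numbers stand for is not stated. RN7SL1 took 0.939 to 2.7% of gene counts and the 10 most abundant genes 5.54 to 8.24%.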
